A study of Apis mellifera with 8 samples.

How the data were processed

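Genomic DNA of honey bees (Apis mellifera) was compared on 4 two-colour Agilent arrays for comparative genomic hybridisation. Per the labels' protocols, the DNA was digested with AluI and RsaI before labelling. Of the 8 samples, 7 carry DNA from Jordan bee legs numbered 1 to 5, and 1 carries DNA from the thorax of a Syriaca bee. The labels give the strains as Jordan bee and Syriaca bee, but the series title names Apis mellifera syriaca alone, so whether the legs and the thorax differ in subspecies is not known. The extraction protocol in the labels speaks of legs, and no separate protocol is given for the thorax. Written as Cy5 over Cy3, the arrays are leg 2 over leg 1 (2L/1L), leg 3 over itself (3L/3L), leg 5 over leg 4 (5L/4L) and thorax over leg 5 (thorax/5L). The scanner table of each array was deposited for both of its samples with identical content, so each array entered the calculations once.

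Per the file headers, the images were read with Agilent Feature Extraction 10.7.3.1, with probe coordinates on genome build Amel_4.0. The processed intensity of each channel was made by that software, per the file headers, with spatial and multiplicative detrending, no local background correction and a linear dye normalisation. Signals near background were replaced there by surrogate values. The mean spot intensity and local background intensity columns are uncorrected, per the file headers. The log10 ratio column holds log10 of the red over the green processed signal, per the file headers, and equalled that value within 0.001 in 99.6% to 99.9% of spots. The deposited value table of the series holds 1 log2 column per sample with its 75th percentile at 0. Its columns correlated with log2 of the same channel's processed signal at r = 0.980 to 0.998 across probes. Their medians were -0.63 for leg 1, -0.57 for leg 2, -0.68 and -0.71 for leg 3 in Cy3 and Cy5, -0.61 for leg 4, -0.61 and -0.65 for leg 5 in Cy3 and Cy5, and -0.85 for the thorax. The submitters' rule for averaging spots in that table is not stated.

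The arrays held 420288 spots. After 1711 control spots were removed, 416477 probe names with 416440 sequences of 60 bases remained. By the array annotation, 315597 probes lay in genes, 92900 between genes, and 7980 on 1235 contigs that the build does not place on its 16 chromosomes. Gene names came from the array annotation. Of 9333 names, 6026 were matched to the RefSeq gene table supplied for the species, 5955 by symbol, 60 by gene identifier and 11 by synonym, and 3307 kept the name in the annotation. The table served for names only. Copies of a probe elsewhere in the genome could not be searched for, so a probe counted as unique where its sequence stood under 1 probe name.

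Log2 of Cy5 over Cy3 was computed from the processed signals and centred on each array's median over chromosome probes. Spots marked as outliers by the software were left out and dim spots were kept. Spots of a probe were averaged. Windows of 10 kb with at least 5 probes took the median of their probes, and genes with at least 3 probes took the mean. This gave 18873 windows on chromosomes, 584 on unplaced contigs and 7357 genes, of which 1904 carried a descriptive symbol. The median was 19 probes per window and 11 per gene.

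The thorax array was tested against the 3 arrays with legs in both channels with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg). The model had an intercept for the dye effect and an indicator of the thorax array. The lone thorax sample was assumed to vary like the legs. Of the 3 leg arrays, 3L/3L carries the same DNA in both channels and so holds no difference between legs. Its log2 ratios had a median absolute deviation of 0.25, against 0.51 on 2L/1L and 0.55 on 5L/4L. The standard errors (SE) and p-values may therefore understate the spread between legs. Arrays were treated as independent, but leg 5 is the Cy3 sample of thorax/5L and the Cy5 sample of 5L/4L, so a departure of leg 5 enters the difference from both arrays with the same sign. Strain as labelled, tissue, individual, slide and scan session all change together on that array, so none of them can be told apart from the others. Array and slide numbers limit the precision throughout. Gene lists were tested with camera (correlation 0.01, and estimated) and fry. A run was at least 5 consecutive probes whose log2 ratio, less the median of the other 3 arrays, was at least 0.5 in either direction. A feature was called at an adjusted p under 0.05.

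The comparisons, the gene lists and the naming rule were fixed before the data were examined. The rule took the 5 highest and 5 lowest windows and genes with a descriptive symbol as values, since none was called, the members of each list with the smallest p, and the 3 runs with the most probes per array. Up to 4 members per list were allowed and 2 are given, a number chosen after values were seen. Naming 10 further windows, from probes well above background in all channels, was also decided after values were seen. Windows and genes named by value also had to lie outside the 3 leg arrays. A feature named over all probes, with under 50% of its probes well above background in the thorax channel, got only a bound on the fold, and no fold where that was under 1. For that bound the brighter legs, on channels put through loess and Aquantile, were set against the higher of the lowest well measured signal and the probe's own, the lower result with and without those 2 steps was taken, and it is open to dye bias, since no dye swap was balanced. The bound carries no error term and no correction for the GC content of probes.

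Alternatives covered normexp background (offset 50), loess, a loess correction for GC and intensity, probe filters, the deposited log2 value table, no dye intercept, the Cy5 channel alone, all channels separately with the array as a random block, eBayes with trend, windows of 5 and 20 kb, and leaving out each leg array. The limma fits, the list tests and the finding of runs were tested on simulated data. The normalisation, the corrections, the probe filters and the fold bounds were not. With independent simulated noise, the window test found 0% of changes of 0.5 on the log2 scale, 58% of changes of 1 and 100% of changes of 2, and the gene test found 2%, 38% and 94%. The probe test found 4% of changes of 2 and 20% of changes of 3. False calls numbered 9 for windows, 9 for genes and 19 for probes, the last more than the changed probes found. On the simulated thorax array, 63.7% of runs of 10 probes changed by 1 were found, beside 291 runs with no signal placed. No probe of the mitochondrial genome is in the array annotation, so the comparison of mitochondrial DNA was not made.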

Results

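The series measured relative DNA copy along the honey bee genome in 7 samples from Jordan bee legs and 1 sample from a Syriaca bee thorax. Legs 3 and 5 were each hybridised in both dyes, so the 7 leg samples stand for 5 numbered legs. Apis mellifera syriaca is the honey bee subspecies of the eastern Mediterranean. Whether the numbered legs came from 1 bee or from several is not stated in the labels. Median uncorrected spot intensities in Cy3 were 696 for leg 1, 320 for leg 3, 1183 for leg 4 and 1418 for leg 5. In Cy5 they were 122.5 for leg 2, 423 for leg 3, 2035 for leg 5 and 140 for the thorax. Between 99.5% and 99.7% of spots were well above background in every Cy3 channel and in legs 3 and 5 in Cy5, but 92.8% were in leg 2 and 73.7% in the thorax. In all 8 channels together, 305169 probes (73.3%) were well above background.

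The series design sets Jordan bee legs against a Syriaca bee thorax. The largest negative windows of thorax against leg lay on short unplaced contigs. Un1121 (117 to 756, Amel_4.0) had 2 of its 5 probes well above background in the thorax, and the mean of the legs was at least 3.81-fold higher there. It was at least 4.27-fold higher for Un4510 (1 to 988, 3 of 8 probes measured), 3.08-fold for Un1833 (1 to 1220, 2 of 8), 1.93-fold for Un4441 (465 to 1104, 1 of 5) and 2.00-fold for Un4784 (117 to 872, 0 of 7). These bounds hold for the mean of the legs and not for each leg. On Un1121, leg 3 stood at -0.22 and -0.32 in Cy3 and Cy5, leg 5 at 2.60 and 2.28 and the thorax at -0.95. On Un4784 leg 3 in Cy5 read -1.96 and the thorax -1.92, but the thorax reading lay near the floor and its true level may be lower. The highest windows were Un1934 (1 to 2148), Un4261 (1 to 872), Un533 (233 to 2032), Un1044 (1 to 1220) and Un5016 (349 to 988). No probe of those 5 windows was well above background in the thorax, so no fold is given. The bounds, on how much higher the legs stood, were under 1 and do not bear on high thorax values.

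Among windows whose values rested on probes well above background in all channels, the highest was on Un179 (10441 to 19432), at 1.39 ± 0.26 over 32 probes (SE, 1 thorax array against 3 leg arrays). Over the whole of Un179, levels relative to chromosome probes were 1.63 in the thorax, 1.62 in leg 1, 1.67 and 1.60 in leg 3 in Cy3 and Cy5, and 1.72 in leg 4. They were 0.90 in leg 2 and 0.34 and 0.95 in leg 5 in Cy3 and Cy5. Between channels after loess and Aquantile, the mean of the legs over the thorax was 0.894-fold for the Un179 window, and 0.712-fold without those 2 steps. A window on chromosome 12 (3911157 to 3919904) that overlaps Fibroin1 and Fibroin2, genes of the silk spun by bee larvae, stood at 0.75 ± 0.30. Windows on chromosome 13 (871448 to 877423) and chromosome 7 (11360928 to 11369027, LOC410067) stood at 0.81 ± 0.31 and 0.70 ± 0.34. Another on chromosome 7 (2170677 to 2180049), which overlaps LOC100577220, LOC409410 and LOC727260, stood at 0.70 ± 0.20. The lowest was Un1529 (1 to 1104) at -2.95 ± 0.31, with a limma adjusted p of 0.0739. Un262 (17053 to 18620) followed at -1.15 ± 0.18, then chromosome 8 (13103363 to 13108769, LOC412161) at -0.90 ± 0.22. On chromosome 13, a window over LOC726434 (2741361 to 2749750) stood at -0.85 ± 0.39, and on chromosome 7 one at 11972495 to 11978238 stood at -0.84 ± 0.19. Over all probes, the windows at 2170677, 2741361 and 11972495 stood at 0.13, -0.53 and -0.43. The last of these turned above 0 with normexp, loess and GC and intensity correction. The chromosome 12 window turned below 0 with the Cy5 channel only. Without the 5L/4L array, the windows at 871448 and 11360928 fell to 0.53 and 0.39 over probes well above background, and the one at 2741361 moved to -0.47.

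None of these windows passed the test. Over all probes, limma called 0 of 19457 windows, 961 had an unadjusted p under 0.05, and the smallest adjusted p was 0.925. Over probes well above background it called 0 of 17344, 382 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0739. At the level of single probes, 0 of 416085 were called by limma and 27712 had an unadjusted p under 0.05. Leaving out the 2L/1L array gave 185 windows, 153 of them on unplaced contigs and 138 of those higher, and 1035 probes, and leaving out the 5L/4L array gave 1 window and 5392 probes. With 5L/4L taken as the odd array in place of the thorax array, 0 windows were called over all probes, but 100 were called over probes well above background, where the thorax array gave 0.

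Fibroin4, another larval silk gene (chromosome 12, 3922799 to 3923758), had the highest value among genes with a descriptive symbol whose thorax ratio lay outside the 3 leg arrays, at 1.19 ± 0.18 (SE, 1 thorax array against 3 leg arrays), with all 3 of its probes well above background. Sur-8 (chromosome 4, 4246001 to 4247260) had 2 of 8 probes measured in the thorax, so no fold is given. Its bound, on how much higher the legs stood, was under 1 and does not bear on a high thorax value. The receptor genes Toll-10 (chromosome 10, 6585415 to 6587754) and Toll-8 (chromosome 10, 6164676 to 6166835) stood at 0.95 ± 0.46 and 0.82 ± 0.52, and at 0.61 and 0.44 without the 5L/4L array. The forkhead gene croc (chromosome 7, 12358959 to 12360758) stood at 0.84 ± 0.34. Between channels after loess and Aquantile, with every probe measured, the mean of the legs over the thorax was 1.00-fold for Toll-10, 0.964-fold for Toll-8, 1.01-fold for croc and 0.757-fold for Fibroin4. Toll-10, Toll-8 and croc thus showed little difference on that scale. Without those 2 steps the folds were 0.685 for Toll-10, 0.759 for Toll-8, 0.751 for croc and 0.498 for Fibroin4, so they depend on the scaling. At the low end, the insulin-like peptide gene ILP-2 (chromosome 14, 4507726 to 4508195) had 1 of 4 probes measured in the thorax and a bound of 1.11-fold lower there. The genes La (chromosome 9, 6036632 to 6038971), which encodes an RNA-binding protein, and abo (chromosome 6, 16085811 to 16087850) had no probe well above background in the thorax. Their bounds were 1.04-fold and 1.11-fold lower there. RpL14 (chromosome 1, 4681692 to 4682171), a gene of the large ribosomal subunit, also had no such probe, and its bound was 1.14-fold lower. For gcl (chromosome 5, 12972097 to 12973116) the bound was under 1 and no fold is given. The mean GC content of the probes was 41.0% to 51.7% in the 5 highest genes and 37.8% to 42.5% in the 5 lowest. By limma, 0 of 7357 genes were called, 350 had an unadjusted p under 0.05, and the smallest adjusted p was 0.995. With normexp background all 5 low genes had values above 0, as did the median of all genes (0.15). That setting adds 50 to each channel, where the median spot intensity of the thorax was 140 over a background of 61. Its signs at dim thorax probes may thus reflect the offset, which was not tested. The bounds take no account of GC content, and at 38.3% GC the median over all probes of the thorax array was -0.33. They therefore show no loss of these genes in the thorax.

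Of the list members named below, only TpnCIIa and nAChRb1 had every probe well above background in the thorax. Under 50% of probes were measured there for Or106 (3 of 8), Or130 (2 of 7), CYP6AS7 (1 of 3), CYP6BC1 (3 of 10), GstO1 (0 of 9), Y-h (13 of 30), Mrjp1 (3 of 7), PGRP-LC (3 of 8), Fem (4 of 10), 5-ht7 (28 of 65) and Vri (2 of 5). Bounds on how much higher the legs stood were 1.03-fold for Or106, 1.13-fold for Mrjp1, 1.06-fold for PGRP-LC and 1.11-fold for Vri. With normexp background the fitted values of these genes lay above 0, so the bounds depend on the processing. For the other genes with under 50% of probes measured the bound was under 1 and no fold is given. The counts and medians of the lists below include such genes. Values given below also take in probes near background where some were not measured in the thorax, namely for Obp4 (2 of 4 measured), Obp3 (2 of 3), Clk (13 of 26), CPR17 (4 of 7), TpnI (29 of 46), GstS4 (2 of 3), RpL23 (2 of 3), Gr10 (30 of 45), Gr3 (4 of 6), CSP4 (4 of 6), Hex70a (6 of 9), Hex70c (16 of 21), CSP3 (3 of 4), PGRP-S1 (4 of 5), apd-3 (15 of 18) and Dsx (120 of 181). For TpnCIIa and nAChRb1, the mean of the legs over the thorax between channels was 0.962-fold and 1.02-fold after loess and Aquantile. Without those 2 steps it was 0.761-fold and 0.787-fold.

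Genes of smell and taste lay mostly below 0 in the thorax, but so did the median of every list tested. Of 28 odorant receptors, 23 were lower and 5 higher, with a median of -0.23 on the log2 scale, where the median of all genes was -0.09. Camera gave an adjusted p of 0.0507, and adjusted p = 0.714 with an estimated correlation. The preset correlation gave 0.00114 with loess, 0.00272 with GC and intensity correction and 0.00218 with probes well above background, and the estimated correlation gave 0.542, 0.437 and 0.541 in these settings. Counts turned to 20 higher and 8 lower with normexp, and to 11 higher and 10 lower with GC and intensity correction on probes well above background. Or106 and Or130 had the smallest p of this list. Of 7 odorant binding proteins, 6 were lower, with a median of -0.37 (camera adjusted p = 0.129), but with normexp 4 were higher and 3 lower. Obp4 stood at -0.80 ± 0.20 with 2 of 4 probes measured in the thorax and a bound of 1.27-fold, and its neighbour on chromosome 9, Obp3, at 0.52 ± 0.19 with 2 of 3. For this list fry's test of change in either direction gave an adjusted p of 0.0242, and its test of change on balance one way gave 0.179. The first of these was 0.934 with normexp, 0.369 with loess, 0.310 with GC and intensity correction and 0.0260 with the deposited value table. All 3 chemosensory proteins were lower, with a median of -0.42 (camera adjusted p = 0.202), among them CSP3 at -0.45 ± 0.18 and CSP4 at -0.42 ± 0.26. Of 5 gustatory receptors, 4 were lower, with a median of -0.16 (camera adjusted p = 0.934), but with GC and intensity correction 5 were higher and 0 lower. Gr10 stood at -0.18 ± 0.18 and Gr3 at -0.31 ± 0.33, the latter at -0.53 without 2L/1L and -0.19 without 5L/4L.

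Genes of detoxification and immunity had medians below 0 as well, as did every list tested and all genes together (-0.09). With normexp background the medians were 0.098 for cytochrome P450, 0.37 for glutathione S-transferases and 0.095 for immune genes. Of 30 cytochrome P450 genes, 20 were lower and 10 higher, with a median of -0.19 (camera adjusted p = 0.361). CYP6AS7 and CYP6BC1 had the smallest p of this list. Of 4 glutathione S-transferases, 2 were higher and 2 lower, with a median of -0.07 (camera adjusted p = 0.934). GstS4 stood at -0.49 ± 0.25. Of 6 antimicrobial peptide and immune pathway genes, 5 were lower, with a median of -0.41 (camera adjusted p = 0.277). The peptidoglycan recognition gene PGRP-S1 stood at -0.42 ± 0.20.

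Of 17 royal jelly and yellow genes, 11 were lower and 6 higher, with a median of -0.22, while camera ranked the list on the higher side (adjusted p = 0.934). Of 5 vitellogenin and storage protein genes, 3 were lower, with a median of -0.18, again with camera on the higher side (adjusted p = 0.934). The hexamerin genes Hex70a and Hex70c stood at -0.24 ± 0.19 and -0.23 ± 0.18. All 4 sex determination genes were lower, with a median of -0.13 (camera adjusted p = 0.934), Dsx at -0.12 ± 0.17.

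Of 22 cuticular protein genes, 11 were higher and 11 lower, with a median of -0.0017, a mean of 0.04 and camera on the higher side (adjusted p = 0.112). The apidermin gene apd-3 stood at 0.35 ± 0.21 and CPR17 at -0.25 ± 0.19. Of 9 muscle structural protein genes, 4 were higher and 5 lower, with a median of -0.0010 and camera on the higher side (adjusted p = 0.698). The troponin genes TpnCIIa and TpnI stood at 0.45 ± 0.19 and -0.36 ± 0.24, the latter at -0.22 without 2L/1L. Of 23 ribosomal protein genes, 15 were lower and 8 higher, with a median of -0.16 (camera adjusted p = 0.361), and RpL23 stood at -0.74 ± 0.19. The direction of this list turned with the setting, to 21 higher and 2 lower with normexp, 17 and 6 with loess and 16 and 7 with GC and intensity correction. Of 18 neurotransmitter receptors, 15 were lower, with a median of -0.11 (camera adjusted p = 0.934). The acetylcholine receptor gene nAChRb1 stood at 0.49 ± 0.20. Of 8 clock and opsin genes, 6 were lower, with a median of -0.09 (camera adjusted p = 0.934), Clk at -0.41 ± 0.20.

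Camera called 0 of the 15 lists, with the correlation preset or estimated. Adjusted over the list alone, 0 genes passed in any list, as over all genes tested, but 1 cytochrome P450 gene passed over its list with the deposited value table. That table also gave a fry adjusted p of 0.0302 for the cytochrome P450 genes, and 0.00887 for clock and opsin genes in the test of either direction. Signs against 0 depend on the setting, since the median of all genes, -0.09, was 0.15 with normexp, 0.08 with GC and intensity correction and 0.11 with that correction on probes well above background. Medians of the lists moved with it. Camera, which sets a list against the other genes, placed the odorant receptors on the lower side in each of these settings. Too few genes were measured to test carboxylesterases (2), histones (2) and venom proteins (1), and 0 were matched for the mitochondrial genome, nuclear oxidative phosphorylation, rRNA and transposon-derived lists.

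The array of leg 5 over leg 4 held the most runs of shifted probes. It had 2561 runs, 1686 losses and 875 gains, against 870 on 2L/1L, 768 on the thorax array and 368 on the array of leg 3 against itself. The last count holds more than the noise of that array, since the median of the other 3 arrays is subtracted there too. The run with the most probes on 5L/4L was a loss of 21 probes in Ptr (chromosome 8, 8714412 to 8715851), at a median of -1.37. Runs of 17 probes in LOC100576196 (chromosome 5, 8811273 to 8813972) and of 16 probes in LOC413955 (chromosome 2, 5593297 to 5596296) stood at -0.79 and -1.42. All probes of these 3 runs were well above background in both channels. On the thorax array, a gain of 20 probes on Un179 (12645 to 18620) stood at 2.14, also with all probes well above background. Over the whole contig the thorax, at 1.63, was level with leg 1 (1.62), leg 3 (1.67 and 1.60) and leg 4 (1.72). Leg 5, the Cy3 sample of that array, was low at 0.34, but read 0.95 in Cy5, and leg 2 read 0.90. Over the whole contig the thorax was thus not above legs 1, 3 and 4. The gain is relative to the other 3 arrays, with whole-contig ratios of -0.29 on 2L/1L and -0.73 on 5L/4L. A low leg 5 therefore cannot be told apart from an effect of the hybridisation or of that subtraction. Runs on Un1283 (465 to 9804, 16 probes) and Un4029 (1 to 2148, 13 probes) were among the 3 with the most probes on 2L/1L, on 3L/3L and on the thorax array. Few or none of their probes were well above background in both channels, so no value is given. The third such run on 2L/1L was a loss of 12 probes on chromosome 1 (11975651 to 11987339, over LOC100578653, LOC410115 and LOC410116) at -0.97, and 25% of its probes were well above background in both channels. On 3L/3L it was a gain of 10 probes in LOC100577687 (chromosome 11, 12434662 to 12435501) at 0.66, relative to the other 3 arrays. In its ratio as measured, 3L/3L had 0 gains and 4 losses, the longest of 5 probes. That gain is thus no feature of leg 3 against itself.

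Restricted to probes well above background in all channels, the runs numbered 1272 on 5L/4L, 403 on 2L/1L, 160 on the thorax array and 139 on 3L/3L. With normexp background there were 4353 on 3L/3L and 5241 on 5L/4L, and with the ratio as measured 4 and 2265. These are counts on 1 array each, with no replicate.

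**Figure D1:**
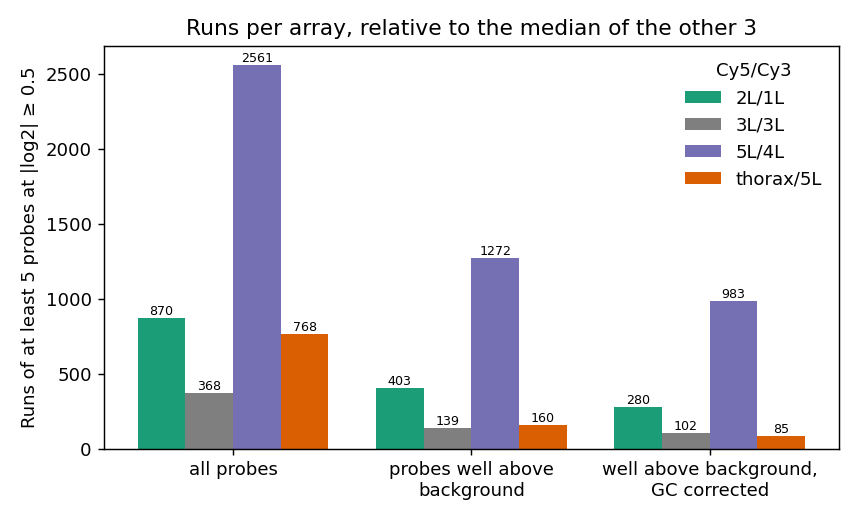
Number of runs of at least 5 consecutive probes that depart by 0.5 or more on the log2 scale from the median of the other 3 arrays, for each array (bars) and for all probes, probes well above background, and those probes after GC and intensity correction. The 5L/4L array has the most runs in each group of bars, 2561, 1272 and 983.

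The spread of log2 ratios was smallest for leg 3 against itself, with a median absolute deviation of 0.25. It was 0.51 on 2L/1L, 0.55 on 5L/4L and 0.57 on the thorax array. Ratios between neighbouring probes spread by 0.22, 0.46, 0.42 and 0.54 on 3L/3L, 2L/1L, 5L/4L and the thorax array. Across windows on unplaced contigs, which are not independent replicates, the thorax array correlated with 2L/1L at r = 0.956, and across windows on chromosomes at r = 0.251. After GC and intensity correction the windows on chromosomes gave r = 0.0470 with 2L/1L, 0.211 with 3L/3L and 0.357 with 5L/4L. Ratios followed the GC content of the probes, with r = 0.293 on 2L/1L, 0.0229 on 3L/3L, -0.190 on 5L/4L and 0.352 on the thorax array across probes. At 35% GC the median ratio was -0.36, -0.06, 0.25 and -0.54 on 2L/1L, 3L/3L, 5L/4L and the thorax array, and at 53.3% GC it was 0.22, -0.03, -0.14 and 0.27.

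**Figure D2:**
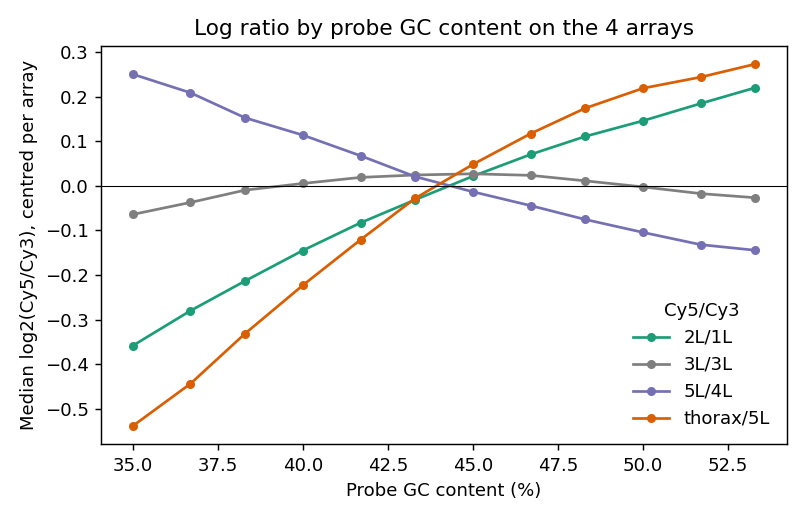
Median log2 of Cy5 over Cy3 (centred per array) against probe GC content in percent, with 1 line per array. The thorax array runs from -0.54 at 35% GC to 0.27 at 53.3% GC, and 5L/4L runs the other way, from 0.25 to -0.14.

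Levels on the contigs with the lowest thorax values also differed between legs. Brighter channels mostly had the higher levels, so differences between legs mostly cannot be told apart from signal strength here. Leg 2 beside the thorax is an exception, given below. Median spot intensities were 1418 and 2035 for leg 5 in Cy3 and Cy5, 1183 for leg 4 and 696 for leg 1. They were 320 and 423 for leg 3 in Cy3 and Cy5, 122.5 for leg 2 and 140 for the thorax. Over the 9 unplaced contigs at least 2 lower on the log2 scale, a group chosen after values were seen, the median level relative to chromosome probes was 2.20 in Cy3 and 1.60 in Cy5 for leg 5. It was 0.95 for leg 4 and 0.87 for leg 1. For leg 3 it was -0.23 in Cy3 and -0.50 in Cy5, for leg 2 it was -0.43, and for the thorax it was -1.24. In the thorax 33.9% of the 59 probes of these contigs were well above background, so its level there is bounded rather than measured for most of them. Leg 2, in the same dye and slightly dimmer, had 71.2% of them well above background. Its median level of -0.43 also lay above the thorax, so median intensity alone does not give that order. On Un4441 and Un1001 leg 2 lay below the thorax, at -2.14 against -1.63 and -3.97 against -3.05.

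**Figure D3:**
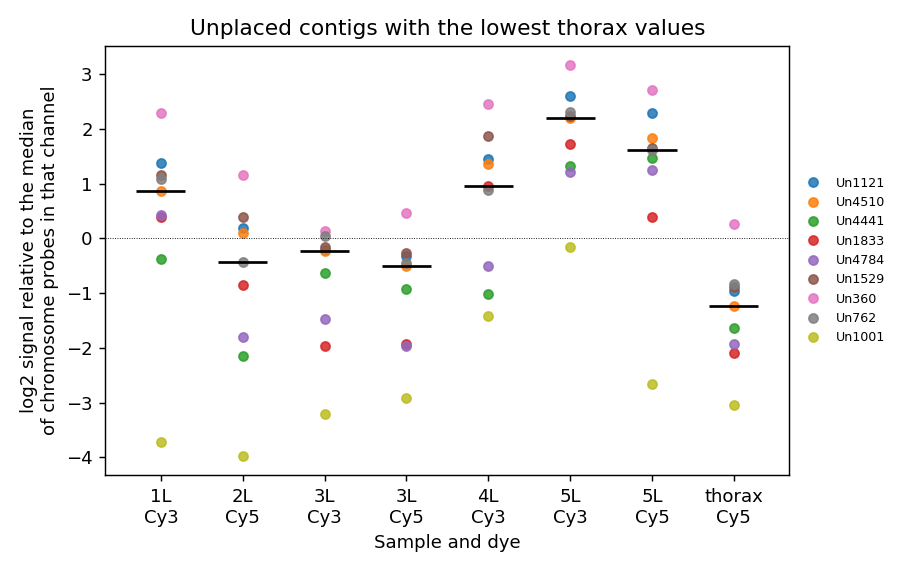
Median log2 signal of each of 9 unplaced contigs (coloured points), relative to the median of chromosome probes in the same channel, for the 8 samples. Black bars are the median over contigs, from 2.20 for leg 5 in Cy3 to -1.24 for the thorax.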

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

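The tests in this part were chosen after the results they bear on had been seen, apart from the 2 tests of leg copy number in the runs. Gaps between the 5 legs were examined for 22 measures, and chance alone marks about 1 in 20 such groups. That share need not hold for windows picked by their thorax values. Legs 1 and 4 were read in Cy3 alone and leg 2 in Cy5 alone, while legs 3 and 5 are means of both dyes. A gap of leg 2 thus cannot be told apart from its dye and weak signal. The share of spots well above background was lowest in leg 2, at 92.8% against 99.5% in the nearest other leg, a gap of 0.979 of the whole range. The level of the window on chromosome 7 at 2170677 to 2180049 was lowest in leg 2, with a gap of 0.887 of the range. The level of the window on chromosome 13 at 2741361 to 2749750 was lowest in leg 4, with a gap of 0.770 of the range.

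High thorax ratios filled 130 windows on unplaced contigs, with 818 probes. More copies in the thorax DNA stay open, since 0.244% of those probes were well above background in the thorax channel and levels near the floor decide nothing. The first test of a technical source, that both channels of the thorax array lay under background, decided nothing, with 74.3% of probes in neither channel against a bound of 80%. A second test was then chosen, the median ratio on 2L/1L, the other array with a weak Cy5 channel, and it was 3.11, so a floor of the weak Cy5 channels may produce these ratios. Because it replaced a test that had not decided, that second value weighs less than a test fixed beforehand.

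Low thorax ratios on 9 unplaced contigs were chosen on the thorax array, whose Cy3 channel holds leg 5. Leg 3 differed from leg 5 by -2.33 with both in Cy5 and from leg 4 by -1.67 with both in Cy3. Strain or tissue as the whole cause would not give such differences between legs. Leg 3 was also dimmer, with median spot intensities of 423 in Cy5 against 2035 for leg 5, and 320 in Cy3 against 1183 for leg 4. The test therefore cannot decide, and strain or tissue stays open. Weak Cy5 signal of the thorax stays open too, since the values above compare legs and 33.9% of the probes were well above background in the thorax. Noise of single hybridisations stays open too, since leg 5 in Cy3 and Cy5 correlated at r = 0.976, but different legs did so at up to r = 0.978. Those correlations are across the 235 unplaced contigs with most probes well above background in at least 1 channel, not the 9 alone. DNA of another organism, or a repeat in variable number, may vary between legs, but the test left it open, with at least 71.2% of probes well above background in every leg channel.

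Runs were most frequent on 5L/4L. Probe GC content and dim probes, as far as the correction and filter remove them, are argued against as the whole cause. After correction and with probes well above background the array had 983 runs, 9.64 times the 102 of leg 3 against itself, and 2L/1L had 280. Of the 983 runs, 891 were losses and 92 gains, so a bias left after the correction stays open. With normexp background the counts were 5241 on 5L/4L and 4353 on leg 3 against itself. Over the probes of these runs, leg 5 in Cy5 departed from the other Cy5 samples by 0.75 in the direction of the run and leg 4 by -0.209, but the runs were selected on this array, which fixes those directions. Copy number of leg 5 or leg 4 stays open, since leg 5 in Cy3 departed by 0.145, on the thorax array, which is among the arrays the runs were compared with.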

How the results depend on the processing

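Chosen after seeing the data were GC correction on probes well above background, limits to chromosomes or to spots measured in a channel, the probe filters of the runs, the probe filter and GC correction of the array spread, and every alternative of the gene lists but the estimated correlation. No paired analysis over replicates was possible because there is 1 thorax sample, which shares its array with leg 5. Slide as a random block could not be estimated with 4 arrays, and slide as a fixed block was not run, since the thorax array lies alone on its slide. The mitochondrial comparison was not run. Gene calls over all genes tested were 0 in all alternatives tried. Alternatives below for windows named from probes well above background are relative to all probes. The dim Cy5 channels of the thorax and leg 2 limit what can be measured, and the causes of the shifts below were not tested. The normexp offset of 50 is large beside the signal of these dim channels, so signs in that setting may reflect it.

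Windows called moved from 0 to 24 with loess (22 higher, all 24 on unplaced contigs), 1 with the deposited value table, 1 with GC and intensity correction on probes well above background, 29 with the Cy5 channel only (all higher, on unplaced contigs) and 7 with separate channels (all lower, on chromosomes). Leaving out leg arrays gave 0 to 185 windows, 185 without 2L/1L (153 on unplaced contigs, 138 of those higher), 0 without 3L/3L and 1 without 5L/4L. Probes called moved from 0 to 1 with normexp, 1 with loess, 1 with GC and intensity correction, 3500 with the value table (161 higher, 3339 lower), 3 with no dye intercept, 3 with the Cy5 channel only and 7817 with separate channels (293 higher, 7524 lower). Leaving out leg arrays gave 0 to 5392 probes, 1035 without 2L/1L and 5392 without 5L/4L, and 0 to 0 genes and lists.

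Lists called by camera moved from 0 to 3 with loess, 2 with GC and intensity correction, 3 with probes well above background and 2 with both, all lower and none with an estimated correlation. Those were odorant receptors (but not with both), chemosensory proteins, immune genes (loess, well above background) and cytochrome P450 (both). Runs on the thorax array, 768, moved to 7937 with at least 3 probes, 10 with at least 10 probes, 3225 at a threshold of 0.3, 126 at a threshold of 1, 1508 with normexp, 160 with probes well above background and 85 with GC correction as well. Its median absolute deviation, 0.57, moved to 0.73 with normexp, 0.45 with loess, 0.45 with probes well above background and 0.46 with GC and intensity correction.

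The median of all genes, -0.09, lay at 0.15 with normexp, 0.05 with loess, 0.08 with GC and intensity correction, 0.02 with probes well above background and 0.11 with both. Signs of fitted values turned as follows, and for genes given only a bound or no fold these are no measured differences. With normexp they were RpL14 0.45, abo 0.28, La 0.40, ILP-2 0.32, gcl 0.61, Or106 0.43, Or130 0.57, Gr10 0.10, Gr3 0.032, CSP3 0.069, CYP6AS7 0.46, CYP6BC1 0.36, GstS4 0.16, GstO1 0.57, Y-h 0.26, Mrjp1 0.0077, PGRP-LC 0.22, PGRP-S1 0.17, Hex70c 0.070, Hex70a 0.089, Fem 0.31, Dsx 0.14, CPR17 0.16, TpnCIIa -0.033, TpnI 0.027, nAChRb1 -0.047, 5-ht7 0.23, Clk 0.095, Vri 0.47 and the window on chromosome 7 at 11972495 to 11978238 0.40. With GC and intensity correction they were Or130 0.057, Gr10 0.052, Gr3 0.23, GstO1 0.37, Hex70c 0.015, Hex70a 0.095, Fem 0.17, Dsx 0.087, CPR17 0.075, 5-ht7 0.075 and the window on chromosome 7 at 11972495 to 11978238 0.083. With that correction on probes well above background they were Gr10 0.11, Gr3 0.42, CYP6BC1 0.30, Y-h 0.10, Mrjp1 0.010, Hex70c 0.056, Hex70a 0.13, Dsx 0.15 and 5-ht7 0.0058. With loess they were GstO1 0.24, Fem 0.13, Dsx 0.032, CPR17 0.025 and the window on chromosome 7 at 11972495 to 11978238 0.16. With the Cy5 channel only they were GstO1 0.32, Hex70a 0.011, Fem 0.057 and the window on chromosome 12 at 3911157 to 3919904 -0.049. Last, CYP6BC1 stood at 0.028 with probes well above background, GstO1 at 0.016 with separate channels, the window on chromosome 7 at 11360928 to 11369027 at -0.034 with the mean of probes, and that at 2170677 to 2180049 at -0.084 with no dye intercept.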

Other observations

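The count of called windows was compared across the 4 choices of the odd array, a test chosen after the counts were seen. All 4 choices gave as many windows as the thorax array, as they must with 0 for the thorax array, and the highest other gave 0. Over spots measured in a channel, 5L/4L as the odd array gave 11 windows, and over probes well above background it gave 100, where the thorax array gave 0 in both. Choices of 1 array in 4 are too few for a share under 0.05.

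Of 342 unplaced contigs with at least 5 probes, 107 had most probes above background in no channel, 114 had most probes above background in all 8, and 121 lay between. On the thorax array 16.9% of probes on unplaced contigs were well above background in neither channel, against 0.0137% of probes on chromosomes.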
